A study of Sus scrofa with 12 samples.

How the data were processed

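Gene expression was compared between 12 libraries, per their labels of pig peripheral blood mononuclear cells (PBMC), 4 from non-treated samples, 4 treated with Salmonella and 4 treated with Salmonella and a miR-124 sponge. A sponge is a synthetic oligonucleotide that binds a microRNA. The titles and column names of the last group name miR-124 and Salmonella but no sponge, and the sponge was taken from the sample descriptions and the series title. Per the labels' protocols, RNA was taken with a PAXgene kit, had an integrity number above 8, and was made into Illumina TruSeq libraries. Per the series labels, these were read as single reads of 50 bases. Per the submitters' processing notes, Bowtie, R 3.4.2 and the genome build Sscrofa11.1 were used. Counting, normalization and gene filtering by the authors are not given in the sources used here.

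The values deposited by the authors were on a log2 scale, with 1 value for each of 7480 gene symbols in each library. The base of the logarithm was not stated and was taken as 2. The values ran from 2.13 to 15.01 and 0 of the 89760 were 0. Read counts were not used here, so the depth behind each value is unknown and no counting error is given. The control and Salmonella columns shared between 1696 and 1809 exact values in each pair of columns, and pairs with a sponge plus Salmonella column were not counted. The highest value of 15.01 was shared by 6 libraries, the Salmonella libraries and sponge plus Salmonella replicates 2 and 4. Sponge plus Salmonella replicate 4 shared its lowest value of 2.60 with Salmonella replicate 1. Sponge plus Salmonella replicate 1 shared its lowest value of 3.20 with control replicate 4. Of the 7480 symbols, 334 (4.47%) were absent from the pig gene tables used here. Examples are HLA-DOA (mean 7.89), LILRA5 (7.70), PRAMEF15 (4.61) and CTAG1B (4.34), and 17 others of the 334 had a mean of at least 8. In the 4 sponge plus Salmonella columns, 65.1% to 71.4% of the values were tied with another gene of the same column, against at most 0.0802% in the other 8. A set of 182 symbols of olfactory receptors, keratin-associated proteins and like genes, taken as silent in blood, had a mean value of 4.63. This level was read as background, and it compresses fold changes of genes near it. The 95th percentile of this silent set was 5.25. Group means were compared with 4.63 only. Fold sizes of genes with a group mean between 4.63 and 5.25 are thus uncertain too, mostly without being marked. Of the 182 symbols, 48 were in the pig gene tables used here. The background and the tests on silent genes thus rest mostly on symbols absent from those tables. These features leave open whether the table holds values from sequencing of these pig libraries.

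Count models were planned, but edgeR and DESeq2 were not used because the values are not counts. limma 3.58.1 in R 4.3.3 was fitted to the deposited log2 values, with all 12 libraries in 1 fit, group means only, and moderated variances with a trend on the mean level. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all 7480 genes were called. For normalized values a pseudocount of 1 and a log2 transform had been planned, and they were left out because the values were already on a log scale. A planned filter on a mean of at least 1 removed 0 genes, since the lowest value was 2.13. On simulated data with the same spread, 200 of 7480 genes were changed, and genes varied independently of each other. A log2 change of 2 was recovered for 93.9% to 98.5% of the changed genes, and a change of 1 for 70.1% to 77.6%. A change of 0.5 was recovered for 26.9% to 37.3%, and 3.70% to 6.12% of the calls were false. Far more genes were called in the data, so these shares do not give the power or the false share of the real calls.

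The groups, the comparisons, the tests, 34 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated. The choice between tests on counts and on normalized values was left to what the table held. The 30 lists with at least 4 measured members were tested with camera, which compares a list's genes with all others, at a preset correlation of 0.01, adjusted over the 30 lists. Only measured members were tested, such as 21 of 39 interferon-stimulated genes and 9 of 20 that respond to interferon gamma. For NF-kB and Toll-like receptor signalling these were 12 of 38, and for reported miR-124 targets 20 of 47. Results for a list do not cover its unmeasured members. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. The genes named in each comparison were those called, with a mean of at least 5 and no overlap between the 2 groups, and with the 10 largest rises and the 10 largest falls. To these were added the 4 members with the smallest p of each list that passed, and of 4 lists whether or not they passed. Those were the lists of interferon-stimulated genes, inflammatory cytokines and chemokines, NF-kB and Toll-like receptor signalling genes, and reported miR-124 targets. Genes outside this rule are said to be chosen after their values were seen, and a gene named or so marked in 1 comparison may be given again in another. Of the genes that the rule names, 1 is not reported here.

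The alternatives included other pseudocounts on the linear scale, quantile normalization, a fit to the 8 libraries of each comparison, stricter thresholds, and leaving out each replicate. Added after seeing the data were sample quality weights, no variance trend, a level filter, median centring, and leaving out pairs of sponge plus Salmonella replicates. A planned search for miR-124 seed sites was not run because 3′ untranslated sequences were not used here. Coordinates were matched by symbol to the pig annotation, which assumes that the values are of pig genes. Libraries with sponge and no Salmonella were not analysed here.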

Results

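Values of 7480 genes were compared between 12 libraries that are, according to the labels, of PBMC from crossbred piglets (Duroc × Landrace × Yorkshire), collected 12 h after treatment. The 3 groups were control, Salmonella, and sponge plus Salmonella, with 4 libraries each. The comparisons ask how blood cells respond to Salmonella and how that response differs with the miR-124 sponge. The median value per library ran from 5.11 to 5.31 log2 units, and the depth of the libraries is unknown. Correlations across genes ran from 0.965 to 0.987 between control libraries, from 0.953 to 0.986 between Salmonella libraries and from 0.964 to 0.981 between sponge plus Salmonella libraries. Between groups they ran from 0.857 to 0.964. The first principal component held 48.6% of the variance and the second 27.4%. Per the labels, the piglets were 4 weeks old and the design held 20 of them, 10 male and 10 female. Nothing in the labels says which animal each library came from, so the p-values measure only the spread between these samples, which may be technical. For the same reason, an unequal split of the sexes between the groups is not excluded.

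**Figure D1:**
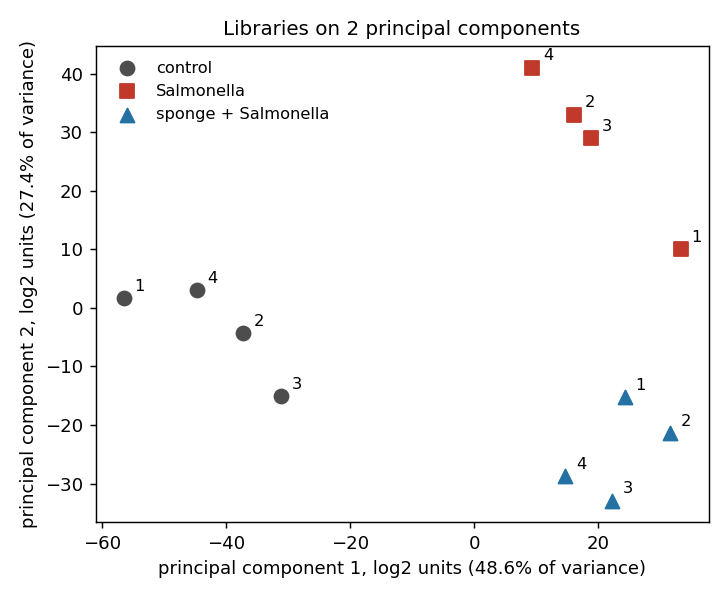
The 12 libraries on the first principal component (x axis, log2 units, 48.6% of the variance) and the second (y axis, log2 units, 27.4%), with 4 points per group numbered by replicate. Within-group correlations ran from 0.953 to 0.987 and between-group correlations from 0.857 to 0.964.

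The comparison of Salmonella with control libraries asks which genes respond to the bacterium. ANKRD22, which encodes an ankyrin repeat protein, rose from 3.15 ± 0.27 to 13.25 ± 0.79 log2 units (SD, n = 4; log2 fold change 10.10 ± 0.96 SE, adjusted p = 3.8e-06). It lies on chromosome 14, 100747955 to 100772412 in Sscrofa11.1, on the same chromosome as the antiviral gene IFIT3 (chromosome 14, 101214730 to 101225169), which rose by 7.47 ± 0.61, adjusted p = 1.6e-06. The chemokine gene CXCL10 (chromosome 8, 71693641 to 71695948) rose by 7.24 ± 0.95, adjusted p = 5.7e-05. IFITM3, which encodes a membrane protein that restricts viral entry, rose by 6.67 ± 0.55, and its fold is capped because it stood at the column maximum of 15.01 in all 4 Salmonella libraries. Log2 rises of the same kind, with SE and n = 4 per group, were seen for BATF2 (5.92 ± 0.46), P2RY14 (5.81 ± 0.56), VAMP5 (5.72 ± 0.49), SLAMF8 (5.71 ± 0.55), GBP6 (5.49 ± 0.51) and SLC6A12 (5.37 ± 0.47). The deepest falls among the named genes were in the calcium channel subunit gene CACNA2D3 (-4.25 ± 0.41, adjusted p = 4.4e-06; chromosome 13, 36222295 to 37025119) and the scaffold gene IQGAP2 (-3.76 ± 0.20, adjusted p = 5.8e-08). Falls were also called for PI3 (-3.08 ± 0.44), FCER1A (-3.02 ± 0.22), OSBPL10 (-2.98 ± 0.22), OLIG1 (-2.94 ± 0.45), GZMK (-2.89 ± 0.28), NLRP12 (-2.83 ± 0.23), ALOX15 (-2.82 ± 0.37) and SPNS3 (-2.80 ± 0.29). The size of a fold is uncertain where a group mean lay below the background of 4.63. In control libraries this held for ANKRD22 (3.15), IFIT3 (4.48), BATF2 (3.70), SLAMF8 (4.11), GBP6 (3.92) and SLC6A12 (4.24) and in Salmonella libraries for CACNA2D3 (3.72), OSBPL10 (3.92), ALOX15 (4.19) and SPNS3 (4.39). FCER1A encodes the alpha chain of the IgE receptor and GZMK a granzyme of cytotoxic lymphocytes.

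Between these groups 2513 of 7480 genes (33.6%) were called, 1175 higher and 1338 lower with Salmonella. An unadjusted p below 0.05 was reached by 3289 genes. The change was at least 1 log2 unit for 600 of the called rises and 483 of the called falls. The 4 values of each group did not overlap for 2661 genes (35.6%), where chance gives 2.86%. Of the 30 lists, 18 passed, 12 higher and 6 lower, and 0 passed with an estimated correlation, where 9 had an unadjusted p below 0.05. By fry 22 passed, 15 higher and 7 lower.

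Interferon-stimulated genes formed the list with the smallest p by camera at the preset correlation, though not with an estimated correlation or by fry. In Salmonella libraries 20 of 21 were higher, 0 were lower and 1 was not called (21 higher and 0 lower when adjusted over the list alone; median log2 fold change 3.39, adjusted p = 1.7e-19, and adjusted p = 0.130 with an estimated correlation). Their mean was 7.13 ± 0.30 in control and 10.34 ± 0.27 in Salmonella libraries (SD, n = 4). Examples are OAS2 (4.56 ± 0.35), PARP9 (4.38 ± 0.36) and ZBP1 (2.84 ± 0.20). Of 9 genes that respond to interferon gamma, 7 were higher, 0 lower and 2 not called (8 higher and 1 lower when adjusted over the list alone; median 2.29; adjusted p = 1.1e-05, and adjusted p = 0.135 with an estimated correlation), among them SOCS1 (4.87 ± 0.42), CD274 (3.41 ± 0.44), IRF1 (2.29 ± 0.21) and FGL2 (2.36 ± 0.20). SOCS1 encodes a suppressor of cytokine signalling and CD274 the ligand PD-L1. Of 20 inflammatory cytokine and chemokine genes, 8 were higher and 1 lower (8 higher and 1 lower when adjusted over the list alone; median 0.35; adjusted p = 0.0108, and adjusted p = 0.135 with an estimated correlation). Besides CXCL10, CXCL9 (2.0 ± 0.39), CCL8 (1.76 ± 0.38), IL1B (1.60 ± 0.28) and IL27 (1.32 ± 0.24) rose. The member called lower was IL1A, chosen after its values were seen. It lay below the background of 4.63 in both groups, so no size is given, and this call ended without control replicate 1 (adjusted p = 0.0509).

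Monocyte and phagocyte genes were higher with Salmonella, and neutrophil and dendritic cell lists were not. Of 9 monocyte markers 6 were higher and 0 lower (9 higher and 0 lower when adjusted over the list alone; median 1.57; adjusted p = 3.3e-05, and adjusted p = 0.130 with an estimated correlation), with CCR2 (3.10 ± 0.35), CLEC7A (2.74 ± 0.41), CX3CR1 (1.57 ± 0.21) and MS4A7 (1.68 ± 0.27) as examples. Of 12 phagocyte antimicrobial genes 6 were higher and 0 lower (6 higher and 0 lower when adjusted over the list alone; median 0.60; adjusted p = 0.00409, and adjusted p = 0.135 with an estimated correlation). These included S100A12 (3.37 ± 0.52), NCF1 (3.01 ± 0.25) and CYBB (2.56 ± 0.28), the last 2 of which encode parts of the NADPH oxidase. Of 11 neutrophil genes S100A12 and, chosen after its values were seen, MPO (1.08 ± 0.36) were higher, and RETN (-1.54 ± 0.40) was lower (2 higher and 1 lower when adjusted over the list alone; median 0.03; adjusted p = 0.558, and adjusted p = 0.752 with an estimated correlation). The neutrophil list did not pass, and the call of MPO ended without control replicates 1, 3 or 4 or Salmonella replicate 4 (adjusted p 0.0745 to 0.0878). Of 8 dendritic cell genes 4 were lower and 0 higher (0 higher and 4 lower when adjusted over the list alone; median -0.58; adjusted p = 0.0112, and adjusted p = 0.135 with an estimated correlation), namely FCER1A, CCR7 and TCF4 (-1.40 ± 0.25) and TLR9 (-0.73 ± 0.19). Of 6 eosinophil and basophil genes 5 were lower and 0 higher (0 higher and 6 lower when adjusted over the list alone; median -1.52; adjusted p = 4.1e-04, and adjusted p = 0.135 with an estimated correlation), namely FCER1A, ALOX15 and IL5RA (-1.77 ± 0.29), CPA3 (-1.26 ± 0.27) and EPX (-0.56 ± 0.15).

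Of 8 platelet genes 5 were higher with Salmonella and 0 lower (5 higher and 0 lower when adjusted over the list alone; median 0.70; adjusted p = 0.00753, and adjusted p = 0.135 with an estimated correlation). They were ITGB3 (1.28 ± 0.28), PPBP (1.13 ± 0.27) and TUBB1 (0.72 ± 0.19), F13A1 (0.60 ± 0.22) and, chosen after its values were seen, GP9 (0.67 ± 0.24). The call of F13A1 ended without control replicates 1, 2 or 4 or Salmonella replicates 3 or 4 (adjusted p 0.0627 to 0.144), and that of GP9 without control replicates 2, 3 or 4 or Salmonella replicates 3 or 4 (adjusted p 0.0893 to 0.129). Of 6 inflammasome genes, IL1B and PYCARD (0.74 ± 0.26) were higher (4 higher and 0 lower when adjusted over the list alone; median 0.40; adjusted p = 0.0319, and adjusted p = 0.165 with an estimated correlation). The call of PYCARD ended without control replicates 2, 3 or 4 or Salmonella replicates 2, 3 or 4 (adjusted p 0.0689 to 0.109).

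Lymphocyte markers were lower with Salmonella. Of 15 T cell markers 14 were lower, 0 higher and 1 not called (0 higher and 14 lower when adjusted over the list alone; median -1.36; adjusted p = 2.6e-07, and adjusted p = 0.135 with an estimated correlation). Their mean fell from 8.93 ± 0.15 to 7.63 ± 0.21 (SD, n = 4), with CD27 (-2.08 ± 0.22), CD2 (-1.63 ± 0.18), BCL11B (-1.56 ± 0.19) and CCR7 (-1.80 ± 0.30) as examples. Of 9 B cell markers 6 were lower and 1 higher (1 higher and 6 lower when adjusted over the list alone; median -1.61; adjusted p = 0.00409, and adjusted p = 0.130 with an estimated correlation), led by CD79A (-2.78 ± 0.20) and CXCR5 (-2.47 ± 0.24). The riser was CD40 (1.86 ± 0.41), a costimulatory receptor, chosen after its values were seen. Of 10 NK cell and cytotoxicity genes 5 were lower and 0 higher (0 higher and 5 lower when adjusted over the list alone; median -0.93; adjusted p = 0.00753, and adjusted p = 0.202 with an estimated correlation), namely GZMK and KLRB1 (-2.09 ± 0.27), GZMH (-1.90 ± 0.52), GZMA (-1.20 ± 0.24) and CTSW (-1.12 ± 0.20).

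Genes of stress, survival and growth moved in both directions. Of 10 heat shock genes 7 were higher and 1 lower (7 higher and 2 lower when adjusted over the list alone; median 1.1; adjusted p = 0.0139, and adjusted p = 0.315 with an estimated correlation), with DNAJA1 (1.28 ± 0.21) and HSPD1 (1.08 ± 0.20) higher and BAG3 (-1.15 ± 0.25) lower. Of 11 apoptosis genes 6 were higher and 2 lower (7 higher and 2 lower when adjusted over the list alone; median 0.91; adjusted p = 0.0289, and adjusted p = 0.135 with an estimated correlation). The death ligand gene TNFSF10 (4.06 ± 0.34) and the survival gene MCL1 (3.08 ± 0.34) rose, while BCL2 (-1.46 ± 0.19) and, chosen after its values were seen, CYCS (-1.04 ± 0.22) fell. Of 15 genes that restrain inflammation 8 were higher and 2 lower (8 higher and 3 lower when adjusted over the list alone; median 0.44; adjusted p = 0.0139, and adjusted p = 0.135 with an estimated correlation). SOCS3 (2.25 ± 0.28), DUSP5 (1.85 ± 0.20) and STAT3 (1.82 ± 0.25) rose, and IL1R2 (-2.26 ± 0.43) and TSC22D3 (-0.98 ± 0.24) fell, the last pair chosen after their values were seen. Of 22 ribosomal protein genes 10 were lower and 1 higher (1 higher and 11 lower when adjusted over the list alone; median -0.52; adjusted p = 0.00361, and adjusted p = 0.202 with an estimated correlation), with RPL10A (-2.0 ± 0.33), RPL4 (-1.97 ± 0.14) and RPLP0 (-1.15 ± 0.16) lower. These genes have many processed copies in the genome, so their values are uncertain. The riser RPLP2 (0.53 ± 0.16) was chosen after its values were seen, and its call ended without control replicate 3 or Salmonella replicate 3 (adjusted p 0.0507 to 0.0711).

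Of 14 cell cycle genes 4 were higher, namely TYMS (1.54 ± 0.31) and TK1 (1.17 ± 0.20) and, chosen after their values were seen, CCNE2 (0.85 ± 0.25) and CCNB1 (0.77 ± 0.13), and MCM5 (-0.83 ± 0.22) was lower (5 higher and 1 lower when adjusted over the list alone; median 0.52; adjusted p = 0.0462, and adjusted p = 0.441 with an estimated correlation). The call of CCNE2 ended without Salmonella replicate 3 (adjusted p = 0.0523). The cell cycle list no longer passed without control replicates 2 or 3 or Salmonella replicates 3 or 4 (adjusted p 0.0746 to 0.148). Of 20 reported miR-124 targets 8 were higher, 1 lower and 11 not called (9 higher and 1 lower when adjusted over the list alone; median 0.36; adjusted p = 0.00471, and adjusted p = 0.135 with an estimated correlation). STAT3 (1.82 ± 0.25), IQGAP1 (1.82 ± 0.35), VAMP3 (1.79 ± 0.20) and PTPN12 (1.48 ± 0.24) rose and LAMC1 (-0.84 ± 0.24) fell. The list of NF-kB and Toll-like receptor signalling genes, with 12 of 38 members measured, did not pass (adjusted p = 0.236), with 5 higher and 2 lower (5 higher and 2 lower when adjusted over the list alone). Its median was -0.00 and its mean 0.73, so the mean rests on TNFAIP6 (5.27 ± 0.47), TLR4 (2.27 ± 0.23) and LY96 (1.96 ± 0.25). IRAK3 (0.81 ± 0.23) and, chosen after its values were seen, IRAK2 (0.83 ± 0.25) also rose, while NFKBIA (-0.89 ± 0.14) and TLR9 fell. The call of IRAK3 ended without Salmonella replicates 2 or 3 (adjusted p 0.0501 to 0.0514), and that of IRAK2 without Salmonella replicate 2 (adjusted p = 0.0569).

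Other named genes also lay near the background. The mean levels of CCNB1, CD274, CXCL9, IL27, OAS2, SOCS1, SOCS3 and TK1 in control libraries and of EPX and LAMC1 in Salmonella libraries lay below the background of 4.63, so the sizes of these changes are uncertain. TLR9 lay below 5.25, the 95th percentile of the silent set, in all Salmonella libraries but replicate 3. The size of its fall is uncertain too. Other genes between 4.63 and 5.25 are not listed.

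**Figure D2:**
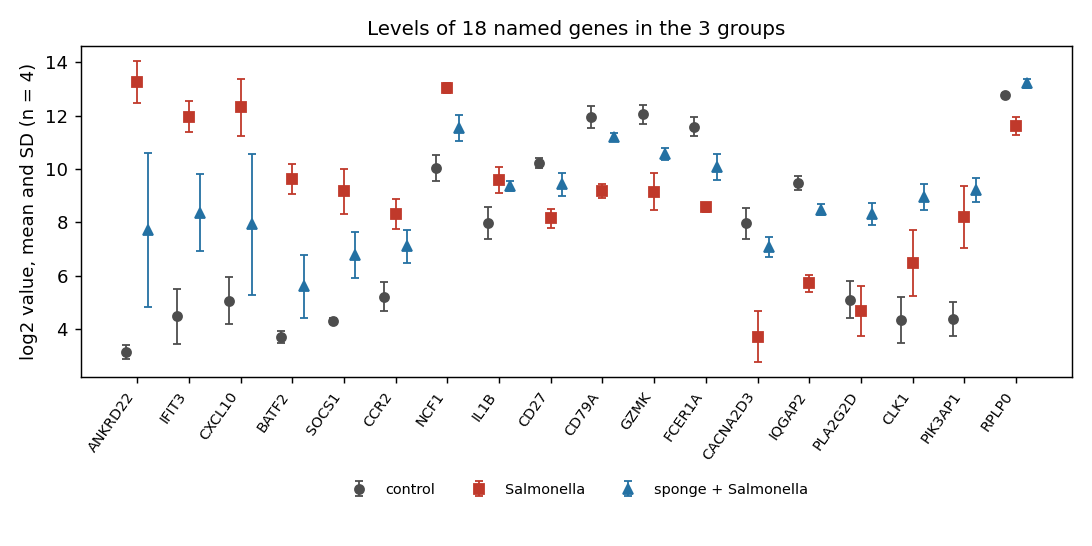
Mean log2 value (y axis) of 18 named genes (x axis) in the 3 groups, with bars of 1 SD over 4 libraries. ANKRD22 stood at 3.15 in control, 13.25 in Salmonella and 7.71 in sponge plus Salmonella libraries.

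**Figure D3:**
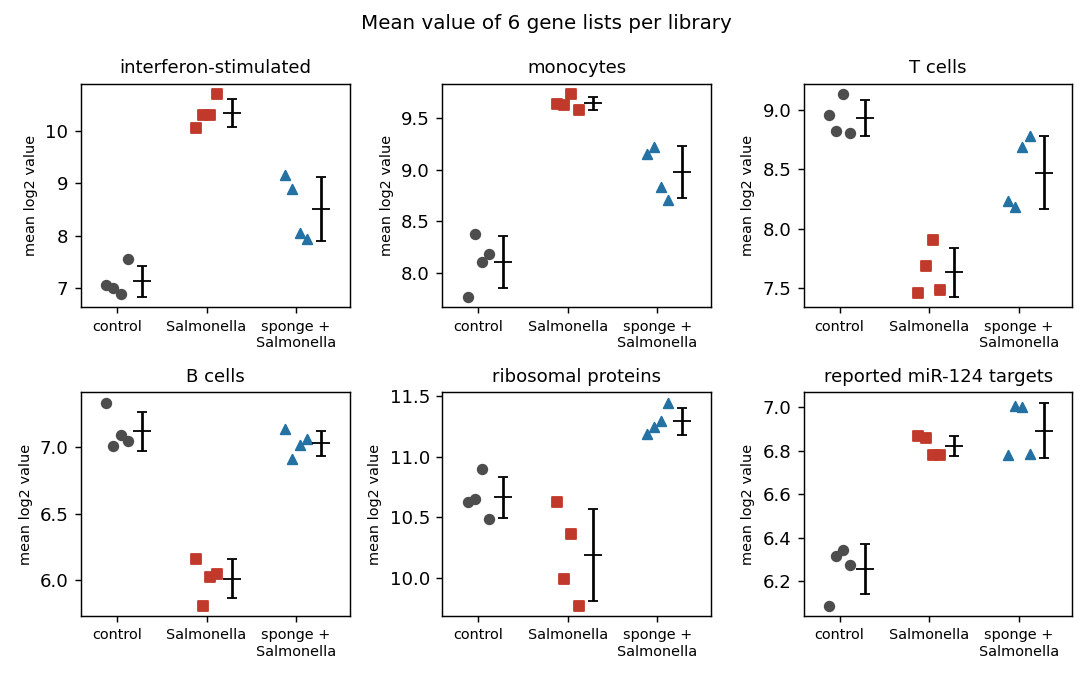
Mean log2 value (y axis) of 6 gene lists per library (points, 4 per group) with the group mean and SD (bars). The interferon-stimulated list stood at 7.13 ± 0.30 in control, 10.34 ± 0.27 in Salmonella and 8.51 ± 0.61 in sponge plus Salmonella libraries.

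The comparison of sponge plus Salmonella with Salmonella libraries asks how the response to the bacterium differs with the sponge. The titles and column names of the sponge libraries name miR-124 and no sponge, so a treatment with miR-124 itself, which would have the opposite aim, is not excluded. Treatment and column type coincide here, because 65.1% to 71.4% of values were tied in the sponge plus Salmonella columns and at most 0.0802% in the others. PLA2G2D, which encodes a secreted phospholipase, was higher with the sponge (log2 fold change 3.63 ± 0.43 SE, adjusted p = 1.4e-04; chromosome 6, 78391063 to 78397394). CACNA2D3 (3.36 ± 0.41, adjusted p = 1.6e-04), OSBPL10 (3.0 ± 0.22, adjusted p = 1.6e-06) and IQGAP2 (2.75 ± 0.20, adjusted p = 1.6e-06) were higher too, and these genes were lower with Salmonella than in control libraries. The means of CACNA2D3 (3.72) and OSBPL10 (3.92) with Salmonella lay below the background of 4.63, so the sizes of these folds are uncertain. Log2 differences upward, with SE and n = 4 per group, were also called for PI3 (2.99 ± 0.44), TSPAN3 (2.48 ± 0.20), CLK1 (2.46 ± 0.53) and OCIAD2 (2.41 ± 0.39). ANKRD22 was lower (-5.53 ± 0.96, adjusted p = 0.00127), at 7.71 ± 2.88 with the sponge (SD, n = 4). BATF2 (-4.01 ± 0.46, adjusted p = 1.2e-04), GBP6 (-3.87 ± 0.51, adjusted p = 2.8e-04) and IFITM3 (-3.80 ± 0.55, adjusted p = 4.1e-04, limited by the column maximum in the Salmonella libraries) were lower as well, as were IFIT3 (-3.58 ± 0.61), P2RY14 (-3.55 ± 0.56), TCN2 (-3.48 ± 0.44), TNFAIP6 (-3.39 ± 0.47), IFI6 (-3.38 ± 0.40) and SLAMF8 (-3.34 ± 0.55). TCN2 encodes a cobalamin carrier and TNFAIP6 a hyaluronan-binding protein.

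**Figure D4:**
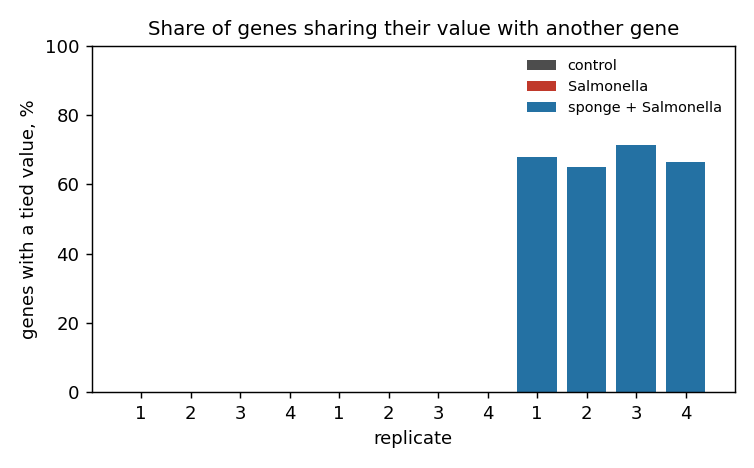
Percent of genes whose value is shared with another gene of the same column (y axis) in each library (x axis, replicate number; bars coloured by group). The 4 sponge plus Salmonella columns stood between 65.1% and 71.4% and the other 8 at no more than 0.0802%.

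With the sponge, 1873 of 7480 genes (25.0%) were called against Salmonella alone, 888 higher and 985 lower. Median centring, chosen after seeing the data, gave 1048 higher and 845 lower. An unadjusted p below 0.05 was reached by 2897 genes. A change of at least 1 log2 unit was called upward for 362 genes and downward for 311. The groups did not overlap for 1780 genes (23.8%), where chance gives 2.86%. Of 30 lists 9 passed, 4 higher and 5 lower, while 0 passed with an estimated correlation, where 4 had an unadjusted p below 0.05, and 14 passed by fry, 5 higher and 9 lower.

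Interferon-stimulated genes were lower with the sponge, 18 of 21 lower, 0 higher and 3 not called (0 higher and 19 lower when adjusted over the list alone; median -1.75; adjusted p = 4.2e-12, and adjusted p = 0.337 with an estimated correlation). The group mean was 8.51 ± 0.61, and the 4 libraries stood at 9.16, 8.89, 8.06 and 7.94. Examples are CMPK2 (-2.88 ± 0.33), OASL (-2.90 ± 0.38) and ZBP1 (-1.62 ± 0.20). Of 9 genes that respond to interferon gamma 6 were lower and 0 higher (0 higher and 6 lower when adjusted over the list alone; median -1.16; adjusted p = 5.5e-04, and adjusted p = 0.355 with an estimated correlation), among them CXCL10 (-4.39 ± 0.95), CD274 (-2.56 ± 0.44), SOCS1 (-2.40 ± 0.42) and IRF1 (-1.53 ± 0.21). Monocyte markers were lower for 5 of 9 and higher for 0 (0 higher and 6 lower when adjusted over the list alone; median -0.64; adjusted p = 0.0411, and adjusted p = 0.353 with an estimated correlation). These were MS4A7 (-1.89 ± 0.27) and CX3CR1 (-1.03 ± 0.21), CCR2 (-1.21 ± 0.35), LYZ (-0.98 ± 0.30) and, chosen after its values were seen, FCN1 (-0.54 ± 0.17). The call of CCR2 ended without sponge plus Salmonella replicate 4 or Salmonella replicates 3 or 4 (adjusted p 0.050 to 0.0699), that of LYZ without sponge plus Salmonella replicates 2, 3 or 4 or Salmonella replicates 1 or 3 (adjusted p 0.0589 to 0.0697), and that of FCN1 without sponge plus Salmonella replicates 3 or 4 or Salmonella replicates 1, 2, 3 or 4 (adjusted p 0.0505 to 0.0923). The monocyte list no longer passed without sponge plus Salmonella replicates 3 or 4 or Salmonella replicates 1 or 3 (adjusted p 0.0568 to 0.0927). Of 12 phagocyte antimicrobial genes 6 were lower and 0 higher (0 higher and 6 lower when adjusted over the list alone; median -0.57; adjusted p = 0.0202, and adjusted p = 0.337 with an estimated correlation), with NCF1 (-1.49 ± 0.25) and CYBB (-1.15 ± 0.28) as examples.

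T and B cell markers were higher with the sponge. Of 15 T cell markers 11 were higher and 0 lower (12 higher and 0 lower when adjusted over the list alone; median 0.82; adjusted p = 7.3e-07, and adjusted p = 0.337 with an estimated correlation), with TCF7 (1.47 ± 0.23), BCL11B (1.44 ± 0.19), CD27 (1.26 ± 0.22) and CD2 (0.82 ± 0.18) as examples. Their mean was 7.63 ± 0.21 with Salmonella alone and 8.47 ± 0.31 with the sponge (SD, n = 4). Of 9 B cell markers 7 were higher and 1 lower (8 higher and 1 lower when adjusted over the list alone; median 1.31; adjusted p = 7.8e-05, and adjusted p = 0.0633 with an estimated correlation), including CD79A (2.03 ± 0.20) and CXCR5 (1.76 ± 0.24). The marker that was lower was CD40 (-1.47 ± 0.41), and its call ended without sponge plus Salmonella replicates 3 or 4 or Salmonella replicates 3 or 4 (adjusted p 0.0509 to 0.0596). Of 6 eosinophil and basophil genes 3 were higher and 0 lower (5 higher and 0 lower when adjusted over the list alone; median 0.72; adjusted p = 0.00523, and adjusted p = 0.337 with an estimated correlation), namely ALOX15 (1.55 ± 0.37), FCER1A (1.51 ± 0.22) and EPX (0.59 ± 0.15). Of 10 NK cell and cytotoxicity genes GZMK (1.41 ± 0.28) and KLRB1 (0.99 ± 0.27) were higher and 0 lower (2 higher and 0 lower when adjusted over the list alone; median 0.20; adjusted p = 0.184, and adjusted p = 0.591 with an estimated correlation). This list did not pass. The call of KLRB1 ended without sponge plus Salmonella replicate 4 or Salmonella replicates 2 or 4 (adjusted p 0.0520 to 0.0587). The 5 plasma cell genes did not pass either (median 0.43; adjusted p = 0.245, and adjusted p = 0.468 with an estimated correlation). Of them IRF4 (1.05 ± 0.36) and SDC1 (0.43 ± 0.15), chosen after their values were seen, were higher and 0 lower (2 higher and 0 lower when adjusted over the list alone). The call of IRF4 ended without sponge plus Salmonella replicates 1, 2, 3 or 4 or Salmonella replicates 2, 3 or 4 (adjusted p 0.0605 to 0.129). The call of SDC1 ended without sponge plus Salmonella replicates 1, 2 or 4 or Salmonella replicates 1, 2 or 4 (adjusted p 0.0634 to 0.135).

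Ribosomal protein genes were higher with the sponge, 16 of 22 higher, 0 lower and 6 not called (17 higher and 0 lower when adjusted over the list alone; median 0.94; adjusted p = 2.9e-09, and adjusted p = 0.133 with an estimated correlation). Examples are RPLP0 (1.59 ± 0.16), RPS6 (1.49 ± 0.22), RPL10A (2.11 ± 0.33) and RPL4 (0.97 ± 0.14), all uncertain because of their copies in the genome. The rises of RPL14 (3.25 ± 0.88, adjusted p = 0.0156; chromosome 13, 24691893 to 24698685) and RPL23 (2.64 ± 0.60, adjusted p = 0.00638) had large SE. RPL14 rose by 2.21 (adjusted p = 0.0305) without Salmonella replicate 4. Of 14 cell cycle genes 6 were lower and 1 higher (1 higher and 8 lower when adjusted over the list alone; median -0.73; adjusted p = 0.00659, and adjusted p = 0.455 with an estimated correlation). CCNB2 (-1.68 ± 0.34), TYMS (-1.43 ± 0.31) and TK1 (-0.93 ± 0.20) were lower, while E2F1 (1.35 ± 0.40), chosen after its values were seen, was higher, and its call ended without sponge plus Salmonella replicates 2 or 3 or Salmonella replicates 2 or 4 (adjusted p 0.0604 to 0.0811).

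The 20 measured members of the 47 reported miR-124 targets did not pass with the sponge (median log2 fold change 0.01, adjusted p = 0.702, and adjusted p = 0.777 with an estimated correlation), with 5 higher, 3 lower and 12 not called (5 higher and 3 lower when adjusted over the list alone). LAMC1 (1.68 ± 0.24) and ACTL6A (0.82 ± 0.17) were higher, as were ROCK1 (1.21 ± 0.39), CAV1 (0.50 ± 0.14) and ITGB1 (0.74 ± 0.25). VAMP3 (-1.39 ± 0.20), STAT3 (-1.24 ± 0.25) and JAG1 (-0.79 ± 0.20) were lower, and ITGB1 and JAG1 were chosen after their values were seen. The call of ROCK1 ended without sponge plus Salmonella replicates 1 or 2 or Salmonella replicates 2, 3 or 4 (adjusted p 0.0730 to 0.110). That of CAV1 ended without Salmonella replicates 2 or 3 (adjusted p 0.0561 to 0.0563). That of ITGB1 ended without sponge plus Salmonella replicates 2, 3 or 4 or Salmonella replicates 1, 3 or 4 (adjusted p 0.0541 to 0.112). The 20 cytokine and chemokine genes did not pass (median log2 fold change -0.28, adjusted p = 0.184, and adjusted p = 0.482 with an estimated correlation), with 6 lower, CXCL10 and CCL8 (-1.83 ± 0.38) and IL27 (-1.11 ± 0.24) among them, and 3 higher (3 higher and 6 lower when adjusted over the list alone). The members called higher were IL18 (0.73 ± 0.21) and, below the background of 4.63 in both groups and so without a size here, IL12B and IL1A. The call of IL18 ended without sponge plus Salmonella replicates 3 or 4 or Salmonella replicates 3 or 4 (adjusted p 0.0551 to 0.0744), that of IL1A without Salmonella replicate 2 (adjusted p = 0.0529) and that of IL12B without Salmonella replicate 3 (adjusted p = 0.0501). The 12 NF-kB and Toll-like receptor signalling genes did not pass either (median log2 fold change -0.10, adjusted p = 0.176, and adjusted p = 0.450 with an estimated correlation), with 4 lower, namely TNFAIP6 and TLR4 (-1.48 ± 0.23), LY96 (-1.45 ± 0.25) and IRAK3 (-0.91 ± 0.23), and 1 higher, TNIP3 (0.38 ± 0.13), chosen after its values were seen (1 higher and 4 lower when adjusted over the list alone). The call of TNIP3 ended without sponge plus Salmonella replicates 3 or 4 or Salmonella replicates 1, 2, 3 or 4 (adjusted p 0.0653 to 0.112).

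When each pair of sponge plus Salmonella replicates was left out, an alternative chosen after seeing the data, calls against Salmonella ended in 6 of 6 fits for LYZ, IL18, IRF4 and ROCK1 and in 5 for E2F1, ITGB1, JAG1, SDC1, RPL14 and TNIP3. They ended in 4 for CAV1 and KLRB1 and in 3 for CCR2, RPL23, CYBB, ALOX15, EPX, IL27, IRAK3, CD40, FCN1, IL1A and the monocyte list. Calls also ended in 2 for IL12B, TK1 and the phagocyte list and in 1 for CLK1, CX3CR1, TYMS, CCL8, CXCL10 and CD2. The highest adjusted p among these was 0.411. The mean levels of ALOX15, EPX, LAMC1, SDC1, TCF7 and TNIP3 in Salmonella libraries lay below the background of 4.63, so the sizes of these changes are uncertain. TK1 lay below 5.25, the 95th percentile of the silent set, in all sponge plus Salmonella libraries, and IL27 in all of them but replicate 1. The sizes of their falls are uncertain too.

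The comparison of sponge plus Salmonella with control libraries asks which differences from untreated cells are present with both treatments. Column type and treatment coincide here too. The signalling adaptor gene PIK3AP1 was higher (log2 fold change 4.81 ± 0.47 SE, adjusted p = 4.0e-05; chromosome 14, 108038396 to 108303942), as were the splicing kinase gene CLK1 (4.6 ± 0.53, adjusted p = 6.3e-05) and ANKRD22 (4.56 ± 0.96, adjusted p = 0.00200). Genes also higher, as log2 difference with SE and n = 4 per group, were SUMO2 (4.47 ± 0.68), ACTR3 (4.44 ± 0.56), GNG10 (4.40 ± 0.48), HSD17B11 (4.31 ± 0.47), DAPP1 (4.2 ± 0.48), GNA13 (4.17 ± 0.57) and RAD21 (4.06 ± 0.64). The control means of PIK3AP1 (4.39), CLK1 (4.35), ANKRD22 (3.15), GNG10 (3.42), DAPP1 (3.58) and GNA13 (4.44) lay below the background of 4.63, so the sizes of these folds are uncertain. SUMO2 and ACTR3 belong to families with close copies, so their values are uncertain. The granzyme gene GZMH was lower (-3.12 ± 0.52, adjusted p = 4.5e-04; chromosome 7, 74723800 to 74727396), with MYOM2 (-3.07 ± 0.58), KRT1 (-3.06 ± 0.62), NLRP12 (-2.53 ± 0.23), SLC2A8 (-2.39 ± 0.29), CEBPE (-2.32 ± 0.35), CCDC127 (-2.19 ± 0.26), RETN (-2.15 ± 0.40) and MXRA7 (-2.12 ± 0.34) lower as well. RNASE3, which encodes an eosinophil ribonuclease, was lower (-2.17 ± 0.64), and its call ended without control replicate 2 (adjusted p = 0.0505). CEBPE encodes a transcription factor of granulocytes.

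Against control, 3057 of 7480 genes (40.9%) were called, 1336 higher and 1721 lower. Median centring, chosen after seeing the data, gave 1470 higher and 1484 lower. An unadjusted p below 0.05 was reached by 3743 genes, and the groups did not overlap for 2973 (39.7%), where chance gives 2.86%. A change of at least 1 log2 unit was called upward for 675 genes and downward for 425. The median over all genes was -0.07, and -0.21 over genes above background. Of 30 lists 6 passed, 6 higher and 0 lower. With an estimated correlation 0 passed, and 2 had an unadjusted p below 0.05, while 15 passed by fry, 9 higher and 6 lower.

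Interferon-stimulated genes stayed above control with the sponge, 15 of 21 higher and 0 lower (16 higher and 0 lower when adjusted over the list alone; median 1.24; adjusted p = 3.2e-07, and adjusted p = 0.554 with an estimated correlation), with IFIT3 (3.88 ± 0.61), PARP9 (3.08 ± 0.36) and OAS2 (2.87 ± 0.35) as examples. Of 9 genes that respond to interferon gamma 5 were higher and 1 lower (5 higher and 1 lower when adjusted over the list alone; median 0.84; adjusted p = 0.0289, and adjusted p = 0.601 with an estimated correlation). The higher ones were SOCS1 (2.46 ± 0.42), FGL2 (1.35 ± 0.20) and IRF1 (0.77 ± 0.21), CXCL10 (2.86 ± 0.95) and, chosen after its values were seen, CXCL11 (0.60 ± 0.20), and the lower one was IRF8 (-0.60 ± 0.18). The call of CXCL10 ended without control replicates 2 or 3 or sponge plus Salmonella replicates 1 or 2 (adjusted p 0.0505 to 0.0753). That of CXCL11 ended without control replicates 1, 2 or 4 or sponge plus Salmonella replicates 1 or 4 (adjusted p 0.0557 to 0.0759). That of IRF8 ended without control replicate 1 or sponge plus Salmonella replicates 2 or 3 (adjusted p 0.0512 to 0.0529). The list itself did not pass without sponge plus Salmonella replicate 1 (adjusted p = 0.0744). Monocyte markers were higher for 5 of 9, namely CLEC7A (2.32 ± 0.41), CCR2 (1.89 ± 0.35), CD163 (1.36 ± 0.30), LYZ (1.05 ± 0.30) and VCAN (0.96 ± 0.24), and lower for 0 (6 higher and 0 lower when adjusted over the list alone; median 0.96; adjusted p = 0.0335, and adjusted p = 0.554 with an estimated correlation), but the list did not pass without sponge plus Salmonella replicates 1 or 2 (adjusted p 0.0593 to 0.0914). Of 8 platelet genes ITGB3 (2.41 ± 0.28) and TUBB1 (1.35 ± 0.19) were higher (2 higher and 0 lower when adjusted over the list alone; median 0.52; adjusted p = 0.0424, and adjusted p = 0.554 with an estimated correlation), and this list did not pass without control replicate 4 or sponge plus Salmonella replicates 1, 3 or 4 (adjusted p 0.0516 to 0.0949).

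Of 20 reported miR-124 targets 9 were higher than in control, 0 lower and 11 not called (9 higher and 0 lower when adjusted over the list alone; median 0.62; adjusted p = 0.00492, and adjusted p = 0.229 with an estimated correlation). IQGAP1 (2.48 ± 0.35), ROCK1 (2.27 ± 0.39), CHSY1 (1.18 ± 0.21) and CAV1 (1.02 ± 0.14) were among them. Their mean was 6.26 ± 0.12 in control, 6.82 ± 0.05 in Salmonella and 6.89 ± 0.13 in sponge plus Salmonella libraries (SD, n = 4). Of 11 apoptosis genes 6 were higher and 1 lower (7 higher and 1 lower when adjusted over the list alone; median 1.1; adjusted p = 0.0117, and adjusted p = 0.229 with an estimated correlation), with PMAIP1 (2.96 ± 0.42), MCL1 (2.53 ± 0.34), TNFSF10 (1.94 ± 0.34) and CASP10 (1.48 ± 0.24) higher. The lower one was CYCS (-0.61 ± 0.22), and its call ended without control replicates 1, 3 or 4 or sponge plus Salmonella replicates 2 or 3 (adjusted p 0.0513 to 0.110). The 20 cytokine and chemokine genes did not pass (median log2 fold change 0.00, adjusted p = 0.222, and adjusted p = 0.601 with an estimated correlation), with 6 higher and 0 lower (6 higher and 0 lower when adjusted over the list alone), such as IL1B (1.37 ± 0.28) and IL18 (0.90 ± 0.21). The 12 NF-kB and Toll-like receptor signalling genes did not pass (median log2 fold change 0.06, adjusted p = 0.745, and adjusted p = 0.846 with an estimated correlation), with 3 higher and 3 lower (3 higher and 3 lower when adjusted over the list alone). TNFAIP6 (1.89 ± 0.47), TLR4 (0.79 ± 0.23) and IRAK2 (0.81 ± 0.25) were higher, and NFKBIA (-1.21 ± 0.14), TLR9 (-0.72 ± 0.19) and, chosen after its values were seen, CHUK (-0.51 ± 0.19) were lower. The call of IRAK2 ended without sponge plus Salmonella replicate 4 (adjusted p = 0.0555), and that of CHUK without control replicates 1, 3 or 4 or sponge plus Salmonella replicates 2, 3 or 4 (adjusted p 0.0613 to 0.127). The 15 T cell markers did not pass (median log2 fold change -0.50, adjusted p = 0.183, and adjusted p = 0.667 with an estimated correlation), with 7 lower and 2 higher, namely CD3D (1.04 ± 0.15) and TCF7 (0.62 ± 0.23), both chosen here after their values were seen. The call of TCF7 ended without control replicates 1, 3 or 4 or sponge plus Salmonella replicates 3 or 4 (adjusted p 0.0734 to 0.114).

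With each pair of sponge plus Salmonella replicates left out, again chosen after seeing the data, calls against control ended in 6 of 6 fits for RNASE3 and CHUK and in 5 for CYCS and TCF7. They ended in 4 for IRAK2 and in 3 for TLR4, CXCL10, CXCL11, LYZ, IRF8, the monocyte list and the platelet list. Calls also ended in 2 for TLR9 and the interferon gamma list and in 1 for IRF1, VCAN and TNFAIP6. The highest adjusted p among these was 0.424. The mean levels of CASP10, CAV1, CD3D, CXCL11, IFIT3, OAS2, PMAIP1, ROCK1 and SOCS1 in control libraries lay below the background of 4.63, so the sizes of these changes are uncertain.

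The Salmonella effect and the sponge effect were compared across the 7480 genes, which are not independent replicates. Of the 1175 genes higher with Salmonella, 445 were lower again with the sponge. Of the 1338 lower with Salmonella, 318 were higher with the sponge. In 20 simulations with the same shared libraries, a test added after seeing the data, changes of the called sizes were placed on genes at random within deciles of mean level. They gave 107 to 139 genes in the first set and 111 to 153 in the second. ANKRD22, CXCL10 and IFIT3 were in the first set, and CACNA2D3, CD79A and CD27 in the second. The correlation was -0.39 (Spearman -0.27). Both effects hold the Salmonella libraries, and 100 simulations with unchanged groups gave -0.50, so the correlation alone does not separate the effects from shared libraries. The covariance was -0.194 against -0.0272 in the simulations, a difference of -0.167. With the Salmonella libraries divided between the effects in 6 ways the correlation ran from -0.51 to -0.14. In the same direction, 82 genes rose with Salmonella and were higher still with the sponge, and 21 were lower in both. For the effects of both treatments against control, the correlation was 0.70, where simulations gave 0.50, and the covariance was 0.453 against 0.0271. The calls shared 624 higher and 871 lower genes, where simulations of the same kind, with the control libraries shared, gave 161 to 198 and 253 to 299.

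**Figure D5:**
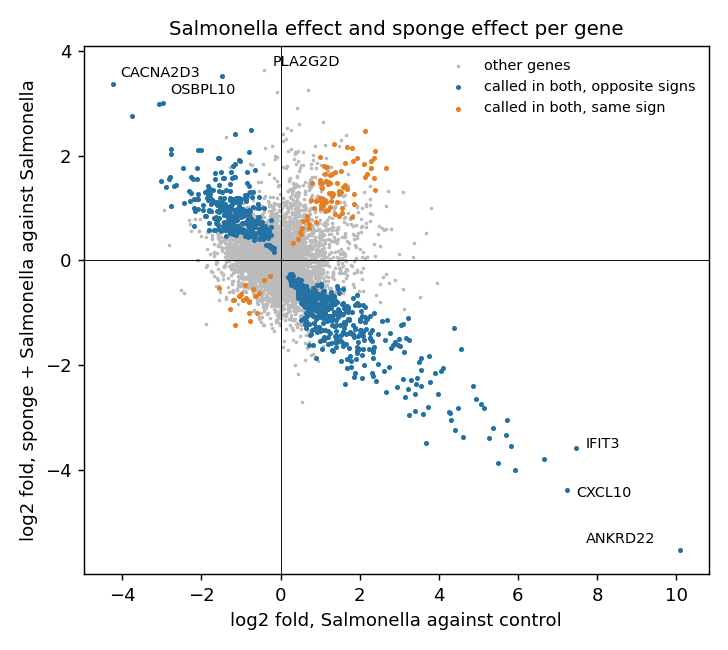
Log2 fold change of each gene with Salmonella against control (x axis) and with sponge plus Salmonella against Salmonella (y axis), with genes called in both comparisons coloured by whether the signs are opposite or the same. There are 445 and 318 genes with opposite signs and 82 and 21 with the same sign.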

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

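The test of tied values in the sponge plus Salmonella columns, both tests of cell composition and the test of shared values in silent genes were chosen only after the result was seen.

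In the groups of 4 libraries, single libraries stood apart for 38 of 581 sets of 4 values, by Dixon's test on the gap to the nearest other library. Chance gives about 1 in 20 groups, here 29.1. Values are log2 units, with the range of the other 3 libraries of the group.

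In control libraries, values that stood apart were those of CCL8 in replicate 3 (5.05, others 5.92 to 6.05), CXCR5 in replicate 1 (9.77, others 8.71 to 8.84), CYBB in replicate 2 (9.23, others 8.60 to 8.67) and E2F1 in replicate 3 (4.64, others 3.98 to 4.06). The same held for FCN1 in replicate 2 (13.57, others 13.47 to 13.49), IL27 in replicate 3 (4.74, others 4.38 to 4.40), ITGB1 in replicate 3 (4.24, others 4.51 to 4.53) and JAG1 in replicate 1 (4.90, others 5.40 to 5.5). Further ones were LY96 in replicate 4 (10.75, others 9.82 to 9.91), MPO in replicate 2 (6.24, others 5.11 to 5.24), ROCK1 in replicate 3 (4.52, others 3.92 to 4.01) and RPL10A in replicate 3 (12.03, others 11.25 to 11.36). Further ones were ZBP1 in replicate 4 (8.75, others 8.19 to 8.25). Means over genes that stood apart were the mean of the erythroid list in replicate 1 (8.72, others 9.28 to 9.32) and the mean of the genes silent in blood in replicate 1 (4.71, others 4.64). With Salmonella, these were CCNB1 in replicate 2 (5.67, others 5.23 to 5.31), CCR7 in replicate 3 (10.92, others 9.55 to 9.73), CD274 in replicate 1 (5.97, others 7.84 to 8.13) and CHSY1 in replicate 3 (9.93, others 9.46 to 9.49). The same held for HK2 in replicate 1 (7.93, others 5.91 to 6.16), MCL1 in replicate 1 (8.77, others 9.44 to 9.54), PARP9 in replicate 1 (10.63, others 9.78 to 9.92) and PFKFB3 in replicate 1 (10.30, others 11.15 to 11.29). Further ones were RPL14 in replicate 4 (3.46, others 7.37 to 7.93), SPNS3 in replicate 1 (5.15, others 4.05 to 4.22), TLR9 in replicate 3 (5.32, others 4.46 to 4.6) and TNFSF10 in replicate 4 (13.46, others 12.60 to 12.74). Means over genes that stood apart were the mean of the NF-kB and Toll-like receptor signalling list in replicate 1 (8.69, others 8.92 to 8.96). With the sponge and Salmonella, they were IL27 in replicate 1 (5.30, others 4.43 to 4.54), MPO in replicate 2 (4.95, others 5.68 to 5.82), PFKFB4 in replicate 3 (10.17, others 9.62 to 9.66) and STAT3 in replicate 1 (7.40, others 7.99 to 8.10). The same held for TK1 in replicate 1 (5.05, others 4.79 to 4.81). Means over genes that stood apart were the mean of the neutrophil list in replicate 1 (7.30, others 7.99 to 8.07), the mean of the oxidative phosphorylation list in replicate 1 (10.41, others 10.13 to 10.16), the mean of the apoptosis list in replicate 2 (7.83, others 7.50 to 7.55), the mean of the p53 response list in replicate 1 (6.16, others 6.43 to 6.47) and the mean of the genes silent in blood in replicate 4 (4.54, others 4.58 to 4.59). No explanation of these single values was tested.

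For the counts of called genes, the 8 libraries of each comparison were divided into 4 and 4 in all 35 ways. The smallest share possible is 1 of 35, below the bound of 0.05 set beforehand. A count reached by the real split alone argues against chance in how these libraries fell into groups, but cannot exclude it. Groups that differ for any reason add that difference to the spread of the other splits, which then call few genes. The test thus does not separate treatment from batch or column type. Chance differences between animals are not excluded, since the animal behind each library is unknown. For Salmonella against control, 1 of 35 splits, the real one, gave as many as 2513 genes, and the highest other gave 0. For sponge plus Salmonella against Salmonella, 1 of 35 gave as many as 1873, and the highest other gave 73. For sponge plus Salmonella against control, 1 of 35 gave as many as 3057, and the highest other gave 1.

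The genes that differed between sponge plus Salmonella and Salmonella libraries may reflect the sponge, or a different making, source or batch of the 4 sponge columns. The lowest share of tied values in a sponge column was 65.1%, and the highest in the other 8 was 0.0802%, so column type and treatment cannot be told apart for these genes. If a different making had moved all genes alike, genes silent in blood would be called as often as expressed ones. Of 182 silent genes 15.9% were called (exact 95% interval 10.9% to 22.1%), against 35.3% of genes with a mean of at least 7. In sponge plus Salmonella against control these shares were 24.2% (18.1% to 31.1%) and 53.1%. In Salmonella against control, where column type does not differ, they were 15.4% (10.5% to 21.5%) and 51.5%. The silent share was thus 0.451 and 0.455 times the expressed share in the comparisons with sponge columns, and 0.299 times in the one without them. The interval of 10.9% to 22.1% lies below 35.3% but reaches both sides of 17.7%, the bound set beforehand at 50% of that rate, so this too stays open. The mean over silent genes was 4.54 to 4.59 in the sponge columns and 4.63 to 4.71 in the other 8, without overlap. Genes taken as silent were thus slightly lower in the sponge columns, which goes with a different making of these columns. How far this holds for expressed genes was not tested.

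Interferon-stimulated genes and monocyte markers were both higher in Salmonella than in control libraries, and a larger monocyte share is a candidate explanation. The interferon-stimulated mean minus the monocyte mean was 0.70 ± 0.31 in Salmonella and -0.97 ± 0.37 in control libraries (SD, n = 4), a difference of 1.67 (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows). If marker values follow cell share, this argues against a larger monocyte share as the whole cause. Compression of marker values at high levels, which would weaken this, was not tested. A lower lymphocyte share alone would raise the markers of other cell types alike, but the monocyte mean minus the eosinophil and basophil mean was 4.21 ± 0.19 against 1.0 ± 0.24, a difference of 3.21 (exact permutation test, two-sided, p = 0.0286), which argues against it. Both differences combine list means that were known when the tests were chosen, so their p-values are not independent support. A response to Salmonella, a change of cell shares as part of the cause, and differences between animals stay open.

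No value was 0, and genes silent in blood had a mean of 4.63, where read counts would give 0 or 1 shared low value. The means of these 182 genes in control and Salmonella libraries correlated with r = 0.588 across genes, which is consistent with a background of its own for each gene, as a hybridisation probe has. The commonest value among silent genes was held by 0.549% of the 182, which is 1 gene, in each control and Salmonella column. No silent gene thus shared its value with another silent gene there. That such sharing would be rare was fixed by the tied share of at most 0.0802% in those columns and adds nothing to it. The near absence of ties there argues against a transform of read counts that gives genes without reads the same value, for those columns only. The sponge plus Salmonella columns, with 65.1% to 71.4% of values tied, were not part of this test. How the values were made, and whether they come from sequencing of these libraries, stays open, and no biological explanation was tested.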

How the results depend on the processing

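The alternatives that left out pairs of sponge plus Salmonella replicates, weighted the samples, dropped the variance trend, kept genes at or above 6 in at least 4 samples, or centred on the median were chosen only after the result was seen.

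Under the alternatives run, 0 lists and 0 named genes reversed, counting only those called in the main fit or in the alternative. Changes of direction without a call were not counted. For example, the NF-kB and Toll-like receptor signalling list in sponge plus Salmonella against control pointed upward by camera and downward by fry. Calls of named genes ended in 88 of 3187 fits by gene and alternative for Salmonella against control, in 389 of 4125 for sponge plus Salmonella against Salmonella and in 301 of 4027 against control. For Salmonella against control, 9 alternatives kept the count of called genes within 1.5 times of 2513 (1798 to 3051), and 10 kept the lists (12 to 22 of 30). For sponge plus Salmonella against Salmonella, 8 kept the genes (1532 to 1963) and 8 the lists (7 to 9). For sponge plus Salmonella against control, 8 kept the genes (2907 to 3319) and 8 the lists (5 to 6). These include the pseudocounts of 1 and 0.1, which could hardly move values of at least 2.13 log2 units. They gave 2508 and 2513, 1864 and 1872, and 3059 and 3057 genes in the 3 comparisons, so their agreement adds little. Median centring raised the share of called genes that were higher with the sponge from 47.4% to 55.4% against Salmonella, and from 43.7% to 49.8% against control.

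Stricter thresholds called fewer genes by construction. A log2 change of at least 1 left 1083, 673 and 1100 genes in the 3 comparisons, in the order given above, and an adjusted p below 0.01 left 1524, 810 and 1840. The level filter tested fewer genes and left 1224 genes and 5 lists for sponge plus Salmonella against Salmonella, and 1795 genes and 1 list against control. With fewer libraries, leaving out sponge plus Salmonella replicates 1 and 3 gave 1153 genes against Salmonella, 2 and 3 gave 1109, 2 and 4 gave 1050, and 3 and 4 gave 774. Leaving out 1 and 4 gave 3 lists against control.

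With an estimated correlation, 0 lists passed in each of the 3 comparisons. The estimates ran from -0.06 (apoptosis) to 0.52 (interferon gamma), with 0.51 for interferon-stimulated genes and 0.38 for T cell markers. The preset was 0.01, and a larger correlation gives a larger p. Lists with a low estimate, such as B cell markers (0.02), did not pass either. The apoptosis list, with an estimate below the preset, had an unadjusted camera p of 0.0316 against 0.0154 at the preset for Salmonella against control. The values were 0.00779 against 0.00117 for sponge plus Salmonella against control, and 0.559 against 0.563 against Salmonella. A larger correlation is thus not the whole cause. Fry gave 14 lists for sponge plus Salmonella against Salmonella and 15 against control. Causes beyond the correlation were not tested.

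Leaving out each replicate gave 1991 to 2419, 1325 to 2013 and 2441 to 2959 genes and 17 to 19, 8 to 10 and 3 to 6 lists. The lowest, 3 lists, came without sponge plus Salmonella replicate 1. The correlation of the Salmonella and sponge effects ran from -0.43 to -0.33. With Salmonella replicates 1 and 2 in the Salmonella effect and the others in the sponge effect it was -0.18, with 1 and 3 -0.14, with 1 and 4 -0.27, with 2 and 3 -0.38, with 2 and 4 -0.51 and with 3 and 4 -0.48. The weak values were those with Salmonella replicate 1 in the Salmonella effect. That library had the lowest mean correlation with its own group (0.962) and stood at 9.99 on the second principal component, where the other Salmonella libraries stood at 29.0 to 41.0; the cause was not tested.

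With the replicate number as a replicate block, 2371, 1706 and 2907 genes were called. The 12 pairs of libraries with the same number correlated, after group means were removed, between -0.360 and 0.377 (mean -0.0161), and 0 libraries were closest to their own number in both other groups, so the numbers were not read as pairs. Alternatives for counts (other size factors, DESeq2, voom, filters on counts) were not run because the values are not counts, and the alternative without a filter is void because the filter removed 0 genes. Folds near the background of 4.63 are limited by it.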

Other observations

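The genes, gene families and patterns in this part were chosen only after the result was seen.

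The metallothionein genes MT1A and MT2A, whose products bind zinc and copper, were higher with Salmonella, with log2 fold changes of 2.75 ± 0.33 SE (adjusted p = 2.8e-05) and 3.14 ± 0.40 (adjusted p = 4.6e-05). Against Salmonella alone they were lower with the sponge, with -2.04 ± 0.33 (adjusted p = 8.5e-04) and -2.6 ± 0.40 (adjusted p = 6.1e-04). The list of 13 acute-phase and metal-withholding genes that holds them did not pass with Salmonella, with MT1A, MT2A and SLC40A1 (1.42 ± 0.39) higher, 0 lower, a median of -0.10, a mean of 0.43 and a test that pointed upward (adjusted p = 0.558). ADM, which encodes the vasodilator adrenomedullin, was higher with Salmonella (3.18 ± 0.34, adjusted p = 1.1e-05) and lower with the sponge (-1.49 ± 0.34, adjusted p = 0.00651). Of 11 glycolysis and hypoxia genes 5 were higher with Salmonella, ADM and P4HA1 (1.86 ± 0.31), PFKFB3 (1.75 ± 0.23), HK2 (1.35 ± 0.43) and PFKFB4 (0.88 ± 0.22), and 2 lower, SLC2A1 (-0.97 ± 0.17) and GAPDH (-0.55 ± 0.14), and the list did not pass (adjusted p = 0.173). The call of HK2 ended without control replicates 1 or 4 or Salmonella replicate 1 (adjusted p 0.0580 to 0.0848). HK2 stood at 7.93 in Salmonella replicate 1 and at 5.91 to 6.16 in the other Salmonella libraries, so the size of its rise rests in part on that library.

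Of 16 oxidative phosphorylation genes 9 were lower in sponge plus Salmonella than in control libraries and 4 higher, namely NDUFB9 (2.90 ± 0.46), UQCRC2 (2.6 ± 0.36), NDUFB10 (1.12 ± 0.29) and NDUFA4 (0.78 ± 0.23), with a median of -0.47 and a mean of 0.08, and the list did not pass in a test that pointed downward (adjusted p = 0.354). The call of NDUFA4 ended without control replicate 1 (adjusted p = 0.0523). The 5 plasma cell genes did not pass with Salmonella (median -1.04, adjusted p = 0.0572, and adjusted p = 0.161 with an estimated correlation), with TNFRSF17 (-2.29 ± 0.45), SSR4 (-1.25 ± 0.18) and XBP1 (-1.04 ± 0.17) lower. At the preset correlation they passed without control replicates 1 or 2 or Salmonella replicates 3 or 4 (adjusted p 0.0394 to 0.0448). The erythroid list, with 3 genes lower and 0 higher, did not pass with the sponge against Salmonella (adjusted p = 0.176, and adjusted p = 0.637 with an estimated correlation). At the preset correlation it passed without sponge plus Salmonella replicate 2 (adjusted p = 0.0496).

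The 82 genes that rose with Salmonella and were higher still with the sponge had median values of 4.43 in control, 5.98 in Salmonella and 7.24 in sponge plus Salmonella libraries. In sponge plus Salmonella libraries, 103 of the genes that rose with Salmonella lay between the other groups and differed from both, as did 89 of those that fell. Against control, 1530 genes were called with both treatments and not with Salmonella alone.

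Over 102 families of symbols with a shared stem, ribosomal proteins of the small subunit were lower with Salmonella (8 of 17 lower, adjusted p = 0.0436) and higher with the sponge against Salmonella (11 of 17 higher, adjusted p = 2.2e-05), and those of the large subunit were higher with the sponge (9 of 17, adjusted p = 0.00018). With an estimated correlation 0 families passed, with adjusted p = 0.905 for the first of these and 0.508 for the others.

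Without pairs of sponge plus Salmonella replicates, calls named in this part ended against Salmonella in 3 of 6 fits for ADM. The highest adjusted p among these was 0.0888. Calls named in this part ended against control in 5 of 6 fits for NDUFA4 and in 3 for NDUFB10. The highest adjusted p among these was 0.128. The mean levels of SLC40A1 in control libraries lay below the background of 4.63, so the sizes of these changes are uncertain.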
